A study of Mus musculus with 3 samples.

How the data were processed

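Total RNA-seq data from 3 biological replicates of 1 group were used: chromatin-fraction RNA of bone-marrow-derived macrophages of C57BL/6J mice, taken 90 minutes after lipid A (100 ng/ml) was added, and depleted of ribosomal RNA, per the labels. Group, replicate number and starting amount of RNA (1 µg, 250 ng and 500 ng for replicates 1, 2 and 3) were taken from the labels, which also give a fragment size range of 250 to 400 and the same donor label for all 3 libraries. With 1 group, no comparison between conditions was made. The comparisons were of genes and gene lists within libraries, of the libraries with each other, and of the 2 quantifications of each library.

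Each library came with 3 tables. The deposited gene and transcript tables with expected counts and TPM were made from an alignment to the transcriptome, per the deposited description files, with the mm10 genome and the GENCODE M21 annotation; the column names are those that RSEM writes, per the file headers. The deposited second transcript table, with estimated counts and TPM, was made from the reads of the library without an alignment file, and its column names are those that kallisto writes, per the file headers. The first kind is called alignment-based here and the second alignment-free. Aligner, versions, trimming, filters, strand settings and the handling of multi-mapping reads are not given in the sources used here. Expected counts are not whole and were not scaled, per the deposited values, whose totals differ between libraries. TPM values were scaled by the authors over all entries of a file, including entries for tRNA genes, ERCC spike-in sequences and the phiX genome, so a change in 1 abundant RNA moves the TPM of all others; each deposited TPM column sums to the same total. The deposited posterior mean TPM was used as an alternative. The deposited score, a posterior standard deviation of each gene's count per the file headers, was not used in a test. All 55536 annotated gene entries were matched to a symbol in the M21 annotation, and 55450 of them had a value in the alignment-free table, whose transcripts were summed to genes. The 26248 tRNA entries, the 96 ERCC entries and phiX were left out of every test.

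Depth was 11277198, 24965749 and 19794886 expected counts in replicates 1 to 3. A count of 0 allows up to 3 counts, which is 0.266, 0.12 and 0.152 counts per 1e+06 counts; these floors cover counting error only, since reads without molecular identifiers are not independent molecules. Replicate 2 had the most counts in all but nearly the same number in protein-coding genes as replicate 3.

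Genes with a mean expected count of at least 10 were tested: 13434 genes, 10520 of them protein-coding. The level of a gene was log2(TPM + 1) minus the median of the 10520 protein-coding genes in the same library (5.5, 3.7 and 4.92 TPM in replicates 1 to 3). The pseudocount of 1 pulls low values together, so differences between low genes are understated. Levels were tested against a bound of 1 log2 unit with limma's treat (version 3.58.1, R 4.3.3, intercept only, moderated variance without a trend), with Benjamini-Hochberg adjustment at 0.05 over all genes and, for fixed lists, over the list alone. Above and below mean called by this test, so a gene can lie more than 2-fold from the reference without a call. The same test was run on the paired difference of the 2 quantifications, over 13427 genes. A level is relative to the expressed genes of the same fraction and depends on which genes enter the median.

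A total of 26 gene lists were fixed before the data were examined: the 7 response lists named in the results, markers of macrophages and of 7 other cell types, and lists for the cell cycle, glycolysis, heat shock, cholesterol synthesis, housekeeping mRNAs, nuclear-retained long noncoding RNAs, long noncoding RNAs of stimulated macrophages, small nuclear and nucleolar RNAs, ribosomal proteins, mitochondrial mRNAs and replication-dependent histones. List levels were compared within each library with 10000 random lists of the same size (two-sided, smallest p 0.0002, Benjamini-Hochberg over lists), and a list was called where all 3 libraries passed. Lists with fewer than 3 members over the filter were described but not tested. Differences between 37 pairs of lists used the median over all annotated members in each library and an exact sign-flip permutation test. The spread of a list was the median SD of log2 TMM-normalised CPM (prior count 2), set against 10000 random lists matched on mean expression in 20 bins. Intron-retaining isoforms were those that M21 types as retained intron; shares were taken for genes with a mean of at least 1 TPM. Composition was given as shares of TPM and of expected counts, with no test.

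Dispersion and TMM factors (1.439, 0.726 and 0.956) came from edgeR 4.0.16 on expected counts rounded to whole numbers. DESeq2 1.42.0 gave alternative size factors (0.916, 1.025 and 1.083) and dispersions. TMM factors multiply the library totals and DESeq2 size factors include them, so these numbers are not on the same scale. With either, 29.6% of genes were more than 2-fold apart between replicates 1 and 2. The planned edgeR alternative for levels could not use glmTreat, which refuses a design with 1 column; its p-values were built from edgeR's quasi-likelihood fit at the bound instead. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for lists and figures.

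The tests were tried on simulated data with known answers: counts for the level and dispersion tests, and normally distributed values for the quantifier, list and GC tests. With changes set in 200 of 10520 genes, the level test recovered 58% of genes set 4-fold above the reference and 100% of those 8-fold above, 0% of those 4-fold below and 92% of those 8-fold below, with 0 of 10320 unchanged genes called; the edgeR version recovered 76%, 100%, 58% and 100%. Genes 4-fold below were thus out of reach of the level test on simulated counts. The quantifier test recovered 99% of 4-fold and 100% of 8-fold differences, simulated with an SD of 0.3 log2 units and no shift between libraries. A coefficient of variation of 0.3 was estimated as 0.299. Of 200 simulated lists of 20 genes, 5.0% were called with no shift, 45.0% with a shift of 1 log2 unit and 97.5% with 2. The GC correction brought a list moved by a GC trend alone from percentile 100.0 to 56.67 and left at 100.0 a list moved by itself.

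Genes printed by name followed a rule set before the data were examined. They are the 10 nuclear-encoded protein-coding and the 10 other nuclear-encoded genes with the highest mean TPM; in each response list the 4 highest and the 2 lowest members over the filter, and in every other list the 3 highest; the 6 genes with the largest SD at a mean count of at least 100, and the 3 such genes of the response lists; the 6 protein-coding genes with the largest difference between quantifications; and the 6 genes of at least 10 TPM with the largest intron-retaining share, and the 4 such genes of the response lists. Not every gene under the rule is printed. Members of a fixed list without a count may be named as such, and Ifnb1, Ifi47 and Egr1 were named after their values were seen. Alternatives were other pseudocounts, count minimums, reference genes, quantifications, normalisations and summaries, and leaving out each replicate. Added after the data were seen were a variance trend, centred quantifier ratios, composition without the locus on chromosome 17 that holds ribosomal RNA, and GC corrections by loess with a span of 0.3 on transcript GC content weighted by TPM (13427 genes). Also settled after values were seen was the limit within which the coefficient of variation counts as unmoved: the SD of the leave-one-out values. Signal tracks and alignments listed in the description files were not used here.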

Results

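RNA bound to chromatin was sequenced from macrophages grown out of the bone marrow of C57BL/6J mice, 90 minutes after lipid A was added at 100 ng/ml. Lipid A is the membrane anchor of bacterial lipopolysaccharide and the part that Toll-like receptor 4 (TLR4) detects; chromatin-fraction RNA holds transcripts still attached to the template together with RNAs that stay in the nucleus. The series held 1 group of 3 biological replicates, and ribosomal RNA was depleted before library preparation. Replicate 1 was made from 1 µg of RNA, replicate 2 from 250 ng and replicate 3 from 500 ng, so that amount and replicate cannot be told apart. Unstimulated cells were not analysed here, so the values are levels after stimulation and not changes caused by it. The deposited expected counts summed to 11277198 in replicate 1, 24965749 in replicate 2 and 19794886 in replicate 3, of which 7709299, 10025928 and 9956941 lay in protein-coding genes. All 3 libraries carried the same donor label, so p-values of the treat and sign-flip tests measure the spread between these samples, which may be partly technical. Those from random lists measure variation among genes and not among samples.

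Genes of the NF-kB module stood far above the typical expressed gene of the fraction. Of 19 NF-kB subunits and feedback regulators, 18 were called more than 2-fold above the median expressed protein-coding gene and none was called more than 2-fold below, with the same 18 and 0 when adjusted over the list alone (1 below without replicate 1). Tnip3, an inhibitor of NF-kB signalling, lay 6.80 ± 1.16 log2 units (SD, n = 3) above that median, Tnfaip3, which encodes the deubiquitinating enzyme A20, 6.41 ± 0.31, the subunit gene Nfkb1 6.01 ± 0.02, and Nfkbia, which encodes the inhibitor IkBα, 5.72 ± 0.21. Cyld, another deubiquitinating enzyme, was the lowest member called, at 1.49 ± 0.34, and Otud1, the member that was not called, measured -1.19 ± 0.26. In limma's treat test against a bound of 1 log2 unit over 13434 genes their adjusted p-values were 0.0466 and 0.304, and those of the 4 highest members were 5.7e-05 or lower.

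Most members of the list of interferon beta and interferon-stimulated genes were also high, but interferon beta itself was not. Of 30 members, 25 were called above the bound and none below, the same counts as when adjusted over the list alone. The guanylate-binding protein gene Gbp5 reached 498 TPM ± 254 (SD, n = 3), Rsad2, which encodes the antiviral enzyme viperin, 433 ± 381, Mx1, an antiviral GTPase, 396 ± 335, and the RNA sensor gene Ifih1 376 ± 214. The 5 members that were not called were Ifnb1, Ifi47, Iigp1, Isg20 and Ifit3b; Ifnb1 and Ifi47 are named because that count is small, after their values were seen. Ifnb1 itself measured 8.32, 2.91 and 4.18 TPM in replicates 1 to 3, a level of 0.02 ± 0.43 log2 units. All 4 of the genes with TPM given above were highest in replicate 1, Rsad2 at 869.59, 165.71 and 264.59 TPM in replicates 1 to 3. The median expressed protein-coding gene was also highest in replicate 1 (5.5, 3.7 and 4.92 TPM in replicates 1 to 3). Raw TPM therefore overstates the excess of replicate 1.

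Cytokine and chemokine genes held high and low members. Of 17 inflammatory cytokines tested, 10 were called above the bound and none below; Il1b stood at 215 TPM ± 32.6 and Tnf, a central inflammatory cytokine, at 189 TPM with values of 201.96, 165.03 and 200.76 in replicates 1 to 3. Tnfsf9, a ligand of the TNF family, stood at 163 TPM ± 38.9 and the macrophage growth factor gene Csf1 at 131 ± 26.6 (SD, n = 3). The 2 lowest that passed the count minimum, Osm and Il23a, were not called (-1.07 ± 0.11 and -0.87 ± 0.89 log2 units). Among 17 chemokines 10 were called above and 2 below. Ccl5 had the highest level, 5.83 ± 0.44 log2 units, followed by Ccl4 at 4.74 ± 0.31, Ccl2 at 4.56 ± 0.27 and Cxcl10 at 4.40 ± 1.06, while Cxcl9 (-1.92 ± 0.44) and Ccl22 (-1.68 ± 0.07) were the 2 called below. Adjusted over the list alone, the counts for both lists were the same; Ccl17 had no count in any library, which allows at most 0.266, 0.12 and 0.152 CPM in replicates 1 to 3. Without replicate 3, 1 chemokine was called below over all genes.

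Immediate early regulators held members on both sides of the typical expressed gene. Of 20 members tested, 7 were called above and 3 below, again the same when adjusted over the list alone. The phosphatase genes Dusp1 and Dusp2 stood at 4.60 ± 0.45 and 4.58 ± 0.34 log2 units, the transcription factor gene Klf6 at 4.11 ± 0.24, and Zfp36, which encodes the mRNA-destabilising protein tristetraprolin, at 3.07 ± 0.52 (SD, n = 3). The 3 called below were the transcription factor genes Egr3 (-2.19 ± 0.22), Fosb (-2.03 ± 0.36) and Egr1 (-1.67 ± 0.24), the last named after its values were seen because the count is small. With no minimum on counts, which lowers the reference median, 15 of 21 members were called above.

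Effector genes and the TLR4 pathway itself completed the response lists. Among 22 antimicrobial and effector genes, 11 were called above and 2 below. Icam1, an adhesion molecule, reached 6.16 ± 0.10 log2 units, the costimulatory receptor gene Cd40 5.84 ± 0.13, Sod2, the mitochondrial superoxide dismutase, 5.36 ± 0.31 and the glycolytic regulator Pfkfb3 5.01 ± 0.33; Serpinb2 (-1.71 ± 0.24) and Arg2 (-1.44 ± 0.19) were called below, with 1 effector gene below without replicate 2 and 0 without replicate 3. Of 26 TLR4 signalling components, 15 were called above and none below, led by genes of signalling kinases: Ikbke at 749.9 TPM ± 71.2, Irak2 at 109.0 ± 11.3, Ikbkb at 108 ± 10.2 and Tbk1 at 92.6 ± 34.9. Tirap and Tab1, the members with the lowest mean TPM, were not called (-0.34 ± 0.31 and -1.34 ± 0.27). Adjusted over the list alone, both lists gave the same counts. With a minimum mean count of 100, which raises the reference median, 7 effector genes and 8 TLR4 components were called above; with no minimum, 17 and 23.

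**Figure D1:**
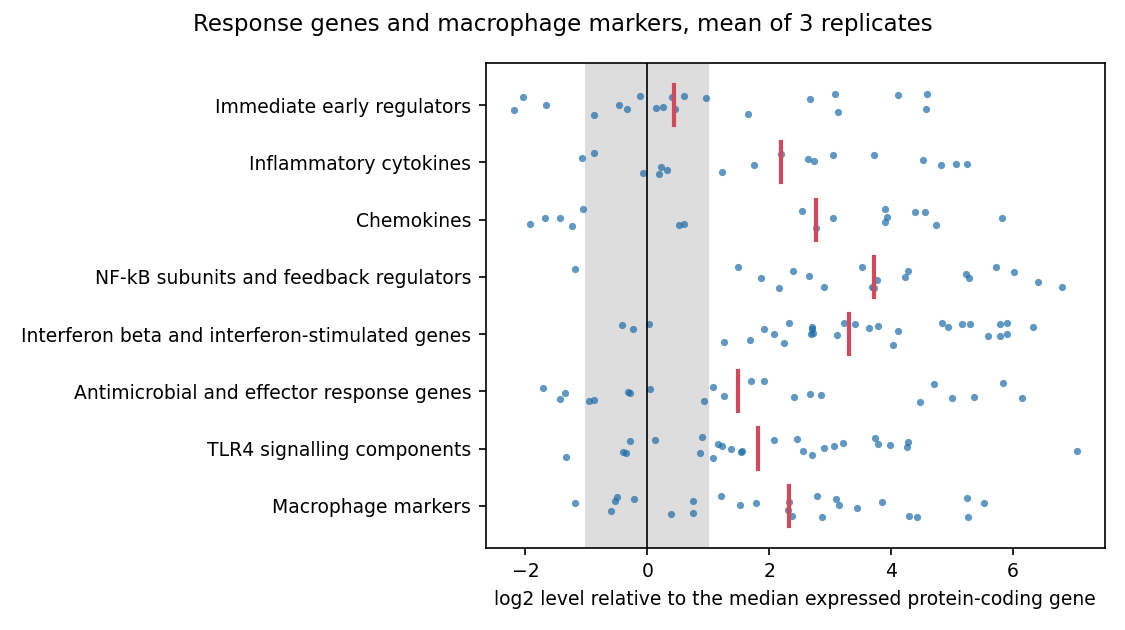
Each point is the mean log2 level of 1 gene over 3 replicates, relative to the median expressed protein-coding gene (horizontal axis, log2 units), for the response lists and the macrophage markers; red bars are list medians and the grey band is within 2-fold of the reference. The list medians run from 0.43 for immediate early regulators to 3.73 for NF-kB subunits and feedback regulators.

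As lists, 6 of the 7 response lists stood above random lists of protein-coding genes in each of the 3 libraries. The median member exceeded that of the random lists by 3.73 ± 0.07 log2 units for NF-kB genes, 3.33 ± 0.87 for interferon genes, 2.97 ± 0.13 for chemokines, 2.15 ± 0.27 for inflammatory cytokines, 1.88 ± 0.04 for TLR4 components and 1.44 ± 0.17 for effector genes (mean and SD over 3 libraries). The highest adjusted p over the libraries was 0.0007 for the NF-kB, interferon and chemokine lists, 0.0077 for cytokines, 0.0021 for TLR4 components and 0.021 for effector genes, from 10000 random lists per library. Immediate early regulators exceeded random lists by 0.47 ± 0.48, with adjusted p between 0.132 and 0.965; with the other quantifier the value was -0.05 ± 0.48, and with no minimum count the list passed in all 3 libraries (2.67, highest adjusted p 0.0182). With the other quantifier, 1 member each of the NF-kB, cytokine, chemokine and TLR4 lists was called below the bound. Within each library the NF-kB list was above the chemokine list by 1.39 ± 0.23 and above the immediate early list by 3.30 ± 0.54 log2 units; in an exact two-sided sign-flip permutation test each gave p = 0.25, the smallest that 3 libraries allow. These percentiles describe the 3 libraries, since genes are not replicates.

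Macrophage markers were abundant, and the median marker of each other cell type that a bone marrow culture could hold was near the floor. Of 25 macrophage markers tested, 16 were called above the bound and none below, also when adjusted over the list alone; with a minimum mean count of 100 it was 11 of 23 above and 3 below (4 below over the list alone), and with the other quantifier 13 above and 1 below. Cybb, a subunit of the phagocyte NADPH oxidase, stood at 285 TPM ± 154, the scavenger receptor gene Msr1 at 224 ± 81.1 and Adgre1, which encodes F4/80, at 221 ± 45.9 (SD, n = 3). Within libraries the median macrophage marker exceeded the median T and NK cell marker and the median mast cell and basophil marker by 4.63 ± 0.23 log2 units each, the median B cell marker by 4.62 ± 0.22, neutrophil markers by 4.60 ± 0.21, erythroid and megakaryocyte markers by 4.57 ± 0.19, stromal and endothelial markers by 4.54 ± 0.18 and dendritic cell markers by 4.50 ± 0.26. Each was higher in 3 of 3 libraries, with an exact two-sided sign-flip permutation p of 0.25, the smallest possible. These sizes rest on the pseudocount of 1: at 0.1 they were between 6.99 and 7.89.

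The few markers of other cell types that passed the minimum count were mostly low. Csf3r, the receptor of granulocyte colony-stimulating factor, was the 1 neutrophil marker of 14 that passed, and it lay above the bound at 26.4 TPM ± 6.1; S100a9 and Ltf were at 0.297 ± 0.376 and 0.28 ± 0.386, and Elane, Ly6g, Mpo and Retnlg had no count. Of 15 stromal and endothelial markers 5 passed and 4 were called below the bound, with Col1a1 at 0.247 TPM ± 0.172, Col3a1 at 0.27 ± 0.392 and Kdr, which was not called, at 1.98 ± 0.865. Of the T and NK cell markers 3 of 14 passed, and 1 was below among all genes, Cd5 at 0.76 TPM ± 0.193; adjusted over the list alone all 3 were below, with Lck at 1.14 ± 0.955 and Cd4 at 0.983 ± 0.790. Over the list alone 2 were below without replicate 1, and 1 without replicate 2, without replicate 3, with posterior mean TPM or with edgeR; against the median of all genes it was 0. Cd22 among the B cell markers and Kit among the mast cell and basophil markers were the single members that passed, and both were below (0.6 ± 0.174 and 0.977 ± 0.856 TPM). Kit's call was lost without replicate 2, without replicate 3, and, when adjusted over all genes, against the median of all genes; with posterior mean TPM both calls were lost, with Cd22 at 3.05 TPM. Batf3 (4.23 ± 0.867) and Zbtb46 (1.38 ± 0.131) for dendritic cells and Pf4 (2.29 ± 2.65) and Itga2b (1.64 ± 0.754) for the erythroid and megakaryocyte list were not called, though without replicate 2 there was 1 call below in the latter list.

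Over all genes, 2864 of 13434 were called above the bound and 2858 below. Counts without 1 library ran from 2448 to 3052 above, and the number below fell to 1571 without replicate 3. Against the median of all genes that passed the filter, rather than of the protein-coding ones, the split was 3196 above and 2084 below. The nuclear-encoded protein-coding genes with the highest mean TPM were Lilrb4a and Lilr4b, receptors of myeloid cells, Tnfaip2, Malt1, Gm21887, Zeb2, Tnip3, Fchsd2, Ahnak and Ikbke. Lilrb4a (ENSMUSG00000112148.1, chromosome 10, 51490956 to 51496611 in mm10) stood at 1889 TPM ± 1011 and 8.25 ± 0.54 log2 units. It is a close paralog of Lilr4b (chromosome 10, 51480632 to 51486703), and both overlap Gm49339 on the same strand, so the split of reads among them is uncertain. Tnfaip2 stood at 1818.51, 1435.72 and 1815.6 TPM in replicates 1 to 3, Malt1, a protease of NF-kB signalling, at 939.7 ± 537, and the transcription factor gene Zeb2 at 854 ± 514.

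Noncoding RNA took a large and unequal part of each library. The Gm26917 locus on chromosome 17 (39843013 to 39846341), which lies beside the annotated ribosomal RNA gene CT010467.1 (39846353 to 39848827) and Gm42418 (39846958 to 39848788), held 8.23%, 43.1% and 33.3% of expected counts in replicates 1 to 3. The 3 entries together held 9.30% of expected counts in replicate 1, 50.8% in replicate 2 and 38.3% in replicate 3, and CT010467.1 and Gm42418 overlap on opposite strands, so reads cannot be assigned between them with certainty. Protein-coding genes held 68.4%, 40.2% and 50.3% of counts; without that locus the shares were 75.4%, 81.6% and 81.5%. Small RNAs, a class that here includes the ribosomal RNA gene CT010467.1, took 64.1% ± 3.18 (SD, n = 3) of TPM but 3.14% ± 1.47 of counts. CT010467.1 alone held 0.18%, 2.85% and 1.31% of counts in replicates 1 to 3, and the whole class 1.73%, 4.66% and 3.03%. The snoRNAs Gm22988, Gm26447 and Snord15b, at 83300 ± 45910, 65150 ± 21120 and 42060 ± 10460 TPM, had effective lengths of 3.4, 1.3 and 3.58 bases, the lengths by which TPM divides the counts. Gm22988 and Gm25835 lie within Eif4a1, Gm26447 within Eif4a2 and Snord15b within Rps3, on the same strand. Ribosomal protein genes and histone genes took 0.130% ± 0.007 and 0.0072% ± 0.0019 of TPM, pseudogenes 0.613% ± 0.312 (7.29% ± 3.12 with the other quantifier), mitochondrial genes 0.052% ± 0.0037 and the remaining annotated classes 0.0004% ± 0.0002.

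**Figure D2:**
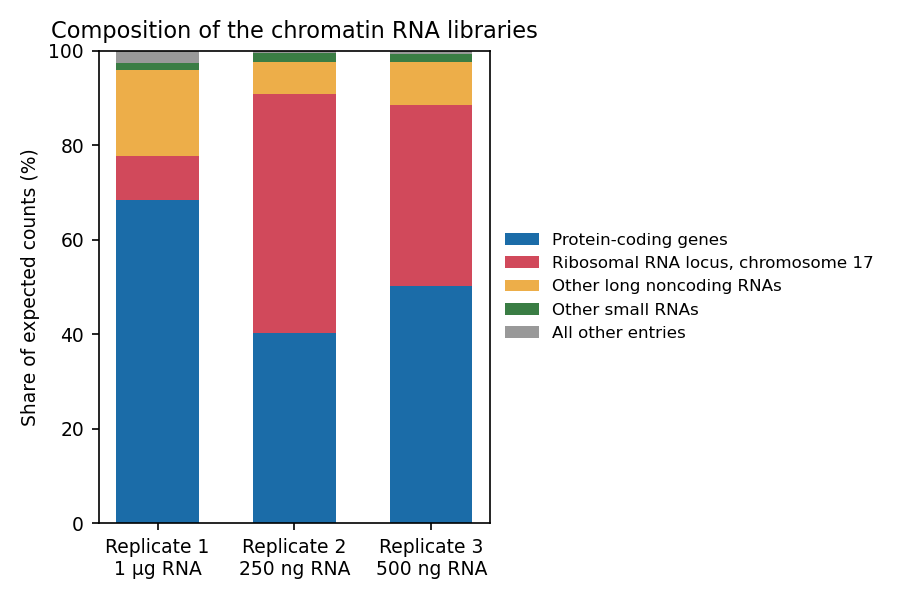
Stacked bars give the percent of expected counts in each class of RNA (vertical axis) for the 3 replicates, labelled with their starting amount of RNA. The ribosomal RNA locus on chromosome 17 took 9.30%, 50.8% and 38.3%, and protein-coding genes 68.4%, 40.2% and 50.3%.

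RNAs known to stay in the nucleus were represented by a few very abundant members. Of 9 nuclear-retained long noncoding RNAs that passed the filter, 6 were called above the bound and none below, also when adjusted over the list alone. Malat1 stood at 13030 TPM ± 7214, Neat1, the scaffold of paraspeckles, at 943 ± 62.1, and Xist, the RNA that coats the inactive X chromosome, at 845 ± 271 (SD, n = 3). Ribosomal protein genes had 34 of 80 members called above and none called below, led by Rps9 at 53.6 ± 9.79 TPM, Rpl10 at 50.6 ± 4.0 and Rpl23 at 40.8 ± 5.25; with no minimum count 80 of 84 were called above, and with a minimum of 100 it was 4 of 57. Against random lists the 2 groups exceeded by 2.59 ± 0.18 and 1.33 ± 0.19 log2 units (highest adjusted p 0.0118 and 0.0007). Mitochondrially encoded mRNAs had 8 of 10 called above, with mt-Co1 at 175.5 ± 26.3 TPM, mt-Atp8, which overlaps mt-Atp6 on the same strand, at 108.5 ± 26.3 and mt-Nd6 at 43.1 ± 8.45 (129, 42.9 and 32.0 TPM with the other quantifier), and exceeded random lists by 2.34 ± 0.35 (highest adjusted p 0.0207). With the other quantifier 5 of 10 were above and the list passed in 2 of 3 libraries (1.55, highest adjusted p 0.1999); with a minimum of 100 it was 2 of 7, and without replicate 1 there was 1 below.

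The direction of the contrasts of nuclear-retained RNAs with ribosomal protein genes and with mitochondrial mRNAs depended on the summary. By medians over all annotated members, the nuclear-retained list lay below ribosomal protein genes by -0.71 ± 0.48 log2 units and below mitochondrial mRNAs by -1.70 ± 0.72; by means over the same members it lay above them, by 0.88 and 0.74. The exact two-sided sign-flip permutation test on the medians gave p = 0.25 for both, the smallest possible. Small nuclear and nucleolar RNAs had 7 of 8 members above, led by both annotated copies of Rmrp, the RNA of RNase MRP, at 94910 ± 60360 and 27350 ± 23730 TPM, which overlap each other, and Rn7s1 at 16440 ± 8577, whose values were the same as those of its copy Rn7s2. Among 3 long noncoding RNAs of stimulated macrophages, Mir155hg, the precursor of microRNA miR-155, lay above at 224 TPM ± 220, and Gm14005 (7.83 ± 6.99) and Mirt1 (2.13 ± 0.809) were not called; with the other quantifier 2 of the 3 were above, and the list level was 2.75 rather than 0.57 log2 units (neither passed). Housekeeping mRNAs had 11 of 15 above and exceeded random lists by 2.02 ± 0.22 log2 units (highest adjusted p 0.0152), led by Fth1, Actb and Eef1a1 at 239 ± 64.3, 225 ± 38.9 and 128 ± 8.15 TPM.

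Isoforms annotated as retaining an intron carried a part of the signal that depended on the unit. Chromatin-fraction RNA also holds RNA that is not yet spliced, and its intron reads can be given to these isoforms. The shares therefore do not measure isoform use. Over 5749 protein-coding genes with such an isoform and a mean of at least 1 TPM, the median share of TPM on those isoforms was 52.6%, 42.7% and 41.7% in replicates 1 to 3 (45.7% ± 6.03, SD, n = 3), and 2446 genes had more than 50%; by expected counts the median was 29.8% and 1625 genes had more than 50%. The highest shares at 10 TPM or more were those of Spaca6 (99.8% ± 0.32), Lilrb4a (98.6% ± 1.24), the interferon-inducible gene Ifi27 (98.5% ± 1.82), the fatty acid transporter gene Slc27a1 (95.9% ± 5.95), the deubiquitinase gene Usp15 (95.5% ± 0.94) and Ppia (94.8% ± 1.99). Spaca6, Lilrb4a and Usp15 overlap other genes on the same strand. In the response lists Tnip3 (94.6% ± 0.72), Dusp1 (92.3% ± 4.58), Sod2 (81.7% ± 1.78) and Irf7 (81.3% ± 1.52) were highest, and Dusp1 overlaps AC122252.1 on the same strand.

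In 2 lists this share differed from random lists matched on expression. Ribosomal protein genes had a median of 60.3% over 64 genes against 46.2% (adjusted p = 0.0028), and macrophage markers 23.2% over 10 genes against 46.7% (adjusted p = 0.0308). The second call was lost with the other quantifier (28.7%, adjusted p = 0.276), with shares of expected counts (14.0%, adjusted p = 0.52) and without replicate 3 (26.9%, adjusted p = 0.0882). None of the 7 response lists passed the threshold, with medians from 20.4% for 4 inflammatory cytokines (adjusted p = 0.161) to 60.2% for 8 chemokines (adjusted p = 0.351); by expected counts the chemokines did, at 68.8% (adjusted p = 0.0252). For single genes the share is an estimate of how reads divide among overlapping isoforms. Some ribosomal protein genes also overlap small RNA genes on the same strand: Rpl10 overlaps Snora70, Rpl23 overlaps Snora21 and Rps3 overlaps Snord15b, while Rps9 overlaps no annotated gene. The effect of such overlaps on the share of the list was not tested.

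Interferon genes differed between replicates more than other genes at their level of expression. The median SD of their log2 CPM, normalised by the trimmed mean of M-values (TMM), over the 3 libraries was 0.63 against 0.33 in matched random lists (30 members, adjusted p = 0.0063). Genes that move together in 1 library count as independent draws in this test, so its p-value does not measure variation between samples. Replicate 1 had 19 of the 30 more than 2-fold above replicate 2 and 15 more than 2-fold above replicate 3, with none more than 2-fold below either; the median differences were 1.21 and 0.90 log2 units. Macrophage markers went the other way, by -0.52 and -0.45, with 7 of 25 more than 2-fold lower in replicate 1 than in replicate 2. So did the 5 stromal markers, by -2.88 and -2.51. After the GC correction the differences from replicate 2 were -0.48 and -2.06. This was not particular to these lists: heat shock genes differed from replicate 2 by -0.74 (-0.77 after the GC correction), glycolysis genes by -0.74 (-0.21) and immediate early regulators by -0.64 (-0.1). Chemokines (0.375), effector genes (0.28), cholesterol synthesis genes (0.46), nuclear-retained RNAs (0.42) and long noncoding RNAs of stimulated macrophages (1.84) were higher in replicate 1. Without replicate 1 the SD of interferon genes was 0.27 against 0.14 (adjusted p = 0.0084). After a correction on transcript GC content, chosen after the GC trend was seen, it was 0.52 against 0.29 (adjusted p = 0.0042). Iigp1, an interferon-inducible GTPase, measured 70.06, 3.32 and 7.06 TPM in replicates 1 to 3. With it, Cd69 (15.75, 1.84 and 3.19) and the cytokine gene Lif (1.84, 10.24 and 7.39) had the largest SDs over the response lists at 100 counts or more. The SDs are of TMM-normalised values, but the TPM values are not corrected for the higher TPM of the typical gene in replicate 1.

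The other response lists did not pass this test: median SDs were 0.54 for chemokines (adjusted p = 0.339), 0.48 for immediate early regulators (0.428), 0.41 for NF-kB genes (0.615), 0.32 for inflammatory cytokines (0.846), 0.26 for effector genes (0.339) and 0.25 for TLR4 components (0.339). Macrophage markers and ribosomal protein genes had 0.36 and 0.35 (adjusted p = 0.874 and 0.615). With the counts of the other quantifier, immediate early regulators passed as well, at 0.61 (adjusted p = 0.0017). Stromal and endothelial markers (5 members, 1.59 against 0.52, adjusted p = 0.0063) and small nuclear and nucleolar RNAs (8 members, 0.89 against 0.37, adjusted p = 0.007) also passed. The stromal call rested on replicate 1, without which the SD was 0.25 (adjusted p = 0.95), and was lost with the counts of the other quantifier (10 members, 0.52 against 0.41, adjusted p = 0.595); the small RNA call was lost without replicate 1 (0.36, adjusted p = 0.0882) and without replicate 2 (0.73, adjusted p = 0.124). Long noncoding RNAs of stimulated macrophages, of which 3 were measured, had 1.01 (adjusted p = 0.0693).

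**Figure D3:**
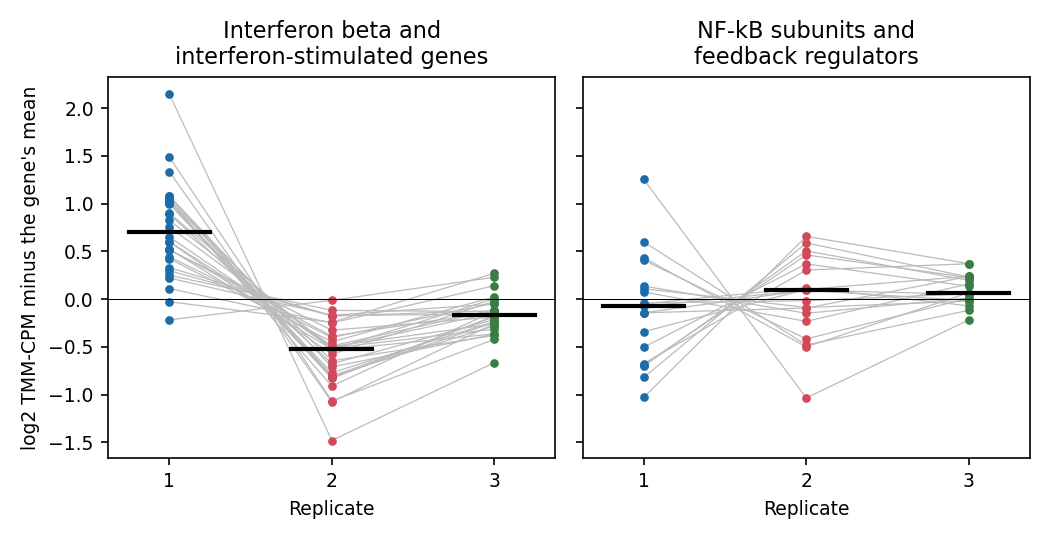
Each line is 1 gene, drawn as its log2 TMM-normalised CPM in each replicate minus its mean over the 3 replicates (vertical axis), for interferon genes (left) and NF-kB genes (right); black bars are medians. In replicate 1, 19 of 30 interferon genes lay more than 2-fold above replicate 2, and none below; of 19 NF-kB genes 2 lay above and 4 below.

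Across all genes, replicate 1 stood apart. In 29.6% of 13434 genes replicates 1 and 2 were more than 2-fold apart, in 22.2% replicates 1 and 3, and in 3.7% replicates 2 and 3; the correlations across genes, which are not independent replicates, were 0.918, 0.939 and 0.982 (Pearson) and 0.919, 0.939 and 0.982 (Spearman). edgeR's common biological coefficient of variation was 0.359 with all libraries and 0.163 without replicate 1, against 0.379 and 0.447 without replicates 2 and 3. The difference between replicates 1 and 2 fell with transcript GC content across genes (Pearson r = -0.542, Spearman rho = -0.572), and so did that between replicates 1 and 3 (-0.521 and -0.549), while that between 2 and 3 had r = 0.206 and rho = 0.246. After a correction on GC content, 18.9%, 13.1% and 3.41% of genes were more than 2-fold apart. The genes with the largest SDs at 100 counts or more were Zc3h11a (0, 20.54 and 18.03 TPM), Gm28048 (28.34, 0 and 2.37), B430305J03Rik (0, 3.75 and 6.56), Gm37110 (0, 7.75 and 3.74), Gm5641 (0, 4.89 and 8.31) and Gm49388 (0, 1.79 and 0.8). Zc3h11a, Gm28048, Gm37110 and Gm49388 overlap other genes on the same strand, Zc3h11a among them a second entry of that name, and each of the 6 was listed at 0 in 1 library.

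The 2 deposited quantifications were compared gene by gene within library. At more than 2-fold, 67 of 13427 genes were higher in the values made from alignments and 569 were lower (limma treat, adjusted p threshold 0.05). The largest differences in protein-coding genes were all lower in the alignment-based values: Klf10 by -4.92 ± 0.93 log2 units, Lsm12 by -4.53 ± 0.81, Atp2b4 by -4.39 ± 1.05, Arhgap39 by -4.35 ± 0.96, E2f7 by -4.25 ± 0.56 and Nudt16 by -4.23 ± 0.59 (SD, n = 3). The median ratio over genes was itself -0.69, 0.03 and -0.31 in replicates 1 to 3, and after centring each library on it 72 were higher and 337 lower. Without replicate 2 the lower count was 874 and without replicate 3 it was 256.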

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

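No test in this part; the values come from entries that no comparison used, and all but the 0 for ERCC sequences exceed the 3 counts that a count of 0 allows. The phiX genome, the usual sequencing control, held 170627, 59140 and 41468 alignment-based expected counts in replicates 1 to 3, which is 1.51%, 0.237% and 0.210% of each library. ERCC spike-in sequences, synthetic RNAs that are added to some libraries as standards, held 9, 22 and 37 alignment-free estimated counts in replicates 1 to 3 and 0 alignment-based expected counts. Entries for tRNA genes held 18, 7 and 9 alignment-based expected counts in replicates 1 to 3. With 1 group of 3 libraries, single libraries were not tested for lying apart and groups could not be compared.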

How the results depend on the processing

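The centred ratios, the GC correction and the composition without the chromosome 17 locus were chosen after the data were seen; the cause of a shift was not tested unless stated. Of the values of the main comparisons under alternatives, 352 stayed on their side of the threshold, or within the replicate spread for values without a test; 32 moved, 10 gained and 14 lost calls, and no call of these comparisons reversed. Among the other results 882 stayed, 263 moved, 37 gained and 49 lost calls, and 2 reversed: the level of cell cycle genes with no minimum count and the spread of stromal markers without replicate 1. Of the TPM levels of named genes 220 moved and 185 did not, and of the composition shares 30 moved and 42 did not. Rescaling TPM over nuclear-encoded protein-coding genes moved 135 TPM levels and left none unmoved. It multiplies each library by a common factor, which sets that outcome, so these 135 do not measure stability. With the other quantifier 64 moved and 71 stayed, and with posterior mean TPM 21 moved and 114 stayed. Differences between lists that changed sign had no call (p of 0.25 or more) and were counted as moved, a choice made after they were seen. With no minimum count the reference median is lower: 7343 genes were above and 0 below, which is fixed by construction, since a gene at 0 TPM then lies at -0.26, with 15 immediate early, 17 effector, 23 TLR4 and 80 ribosomal protein genes above, immediate early regulators passed as a list (2.67 log2 units, adjusted p = 0.0182), and cell cycle genes turned to 0.38. With a minimum of 100, fewer genes were tested and 1317 were above and 784 below, with 7 effector, 8 TLR4 and 4 ribosomal protein genes above; 0.9% of genes were over 2-fold apart between replicates 2 and 3. Leaving out 1 replicate gave 1571 to 3338 genes below, a coefficient of variation of 0.163 to 0.447, a macrophage intron-retaining share of 15.8% to 26.9%, and a stromal spread of 0.253 to 2.034.

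At a pseudocount of 0.1, which stretches low values, and by means over members, log2 differences were 7.70 and 4.08 for macrophage markers minus neutrophil markers, 7.89 and 4.28 for macrophage markers minus T and NK cell markers (4.38 with the other quantifier), 7.85 and 4.40 for macrophage markers minus B cell markers, and 6.99 and 4.05 for macrophage markers minus dendritic cell markers. They were 7.89 and 4.39 for macrophage markers minus mast cell and basophil markers, 7.46 and 4.13 for macrophage markers minus erythroid and megakaryocyte markers, and 7.22 and 4.27 for macrophage markers minus stromal and endothelial markers. Nuclear-retained RNAs exceeded ribosomal protein genes by 0.88 and mitochondrial mRNAs by 0.74 by means, and by -0.91 the latter with the other quantifier. Chemokines minus housekeeping mRNAs turned from 0.32 to -0.68 with the other quantifier and -0.90 by means.

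With the other quantifier's counts the immediate early spread was 0.612 and passed, as did histone genes (0.627, adjusted p = 0.046) and erythroid markers (1.108, adjusted p = 0.0312), of which too few passed the filter before. Without replicate 1, cholesterol synthesis genes (0.345, adjusted p = 0.0154) and mitochondrial mRNAs (0.393, adjusted p = 0.0147) passed. After GC correction 18.9% and 13.1% of genes differed over 2-fold between replicate 1 and replicates 2 and 3. Quantifier differences were 936 lower at a pseudocount of 0.1, 0 higher and 1 lower with no filter, 337 lower when centred, and 256 to 874 lower without 1 replicate. By expected counts the intron-retaining share was 29.8% over all genes, 68.8% for chemokines and 14.0% for macrophage markers (28.7% with the other quantifier). Protein-coding genes held 52.9% by counts, 28.8% by the other quantifier's TPM and 79.5% of counts without the locus. Small RNAs held 3.14%, 46.2% and 2.72% by these measures, of which only the last leaves out CT010467.1. Long noncoding RNAs held 42.7% by counts but 16.1% of counts without the locus, whose Gm26917 and Gm42418 are annotated as long noncoding. Mitochondrial RNA held 0.0479% and 0.073% of counts with and without the locus. Interferon genes kept their call for spread in all 6 alternatives run, with SDs from 0.27 to 0.86. Depth sets what a count of 0 can exclude, 0.266, 0.12 and 0.152 CPM in replicates 1 to 3; no setting varied depth.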

Other observations

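The correction on GC content and the composition without the ribosomal RNA locus were chosen after the trend and the locus were seen, and so were the tests of cytoplasmic carry-over and of the starting amount. The tests of GC content and gene length on interferon genes and of nuclear copies of mitochondrial genes were written before their results were seen, but after replicate 1, its high interferon and AT-rich genes, and mitochondrial mRNAs at 0 had been noticed.

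The level of cell cycle genes depended on the count filter. Of 11 that passed it, 1 was called above the typical expressed gene and 6 below (7 below when adjusted over the list alone; 2 below either way without replicate 3). Mki67, a marker of proliferating cells, stood at 48.0 TPM ± 12.04 (SD, n = 3) and was the member above, and Pcna (14.6 ± 9.85) and Top2a (3.26 ± 1.90) were not called. The list lay 1.51 log2 units under random lists (-1.51 ± 0.23, adjusted p between 0.0098 and 0.0451 over 3 libraries), a call lost with posterior mean TPM (-1.17, highest adjusted p 0.188). With no minimum count it was 0.38 with 2 of 18 called above, and with a minimum of 100 the 3 members left had 1 above and 0 below (1 below over the list alone). Histone genes of the replication-dependent kind had 0 of 16 called above and 4 below, and passed in 1 of 3 libraries (-1.11 ± 0.49, adjusted p between 0.0046 and 0.346). With the other quantifier 10 of 16 were below and the list passed in all 3 (-1.88, highest adjusted p 0.0171), and with no minimum count it was 0.33 and passed in none. Hist1h4m, Hist2h2aa2 and Hist3h2a, the highest, were not called, at 7.86 ± 2.38, 6.46 ± 1.47 and 4.25 ± 3.03 TPM. Adjusted over the list alone the histone counts were the same, with 2 below without replicate 3.

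Glycolysis genes had 8 of 15 members called above and none below (9 above when adjusted over the list alone), led by the hexokinase genes Hk3 (191 TPM ± 7.78) and Hk2 (56.4 ± 3.01) and the phosphofructokinase gene Pfkp (134 ± 50.6), and the list passed in 2 of 3 libraries (1.49 ± 0.23 log2 units, adjusted p between 0.0171 and 0.0984). Heat shock and chaperone genes had 5 of 12 called above and 3 below, and without replicate 3 they had 4 above and 0 below (1 below over the list alone). Hspa8 stood at 47.8 ± 12.3 TPM, Dnaja1 at 41.6 ± 28.1 and Hspa5 at 33.9 ± 8.04, and the list did not differ from random lists (-0.26 ± 0.10, adjusted p between 0.665 and 0.881). Cholesterol synthesis genes had 5 of 14 called above and 1 below (2 below without replicate 1), with Insig1 at 30.6 ± 13.9 TPM (list level -0.08 ± 0.19, adjusted p between 0.744 and 0.914). Adjusted over the list alone, both of these lists gave the same counts.

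With genes in 4 equal groups by GC content, those in the lowest (median 41.6%) were higher in replicate 1 than in replicate 2 by a median of 0.71 log2 units, and those in the highest (median 56.5%) differed by -0.72; against replicate 3 the values were 0.55 and -0.60, and between replicates 2 and 3 they were -0.13 and 0.13. After the GC correction, heat shock (0.61, adjusted p = 0.0098), mitochondrial (1.00, adjusted p = 0.0042) and histone lists (0.67, adjusted p = 0.0385) also varied between replicates more than matched lists. Before the correction their SDs were 0.49, 0.45 and 0.67, and none passed the same test (adjusted p = 0.615, 0.765 and 0.338). The correction thus widened the heat shock and mitochondrial spreads.

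The interferon genes varied between replicates more than matched genes, with replicate 1 highest. A GC bias of the libraries as the whole source is argued against by the list's place at percentile 99.99 of matched random lists after the GC correction (median SD 0.52 against 0.29). Differences between libraries hardly followed gene length across genes (Spearman rho -0.037, -0.03 and 0.032 for replicates 1 and 2, 1 and 3, and 2 and 3). A correction on length thus had little to remove and could decide little: the list stayed at percentile 100.0 (0.63 against 0.33). The GC correction did lower the median difference between replicates 1 and 2 from 1.21 to 1.03 log2 units, so part of it may follow GC content. Cultures that differed in their interferon response could give such values, but each replicate also had its own amount of RNA, and no biological explanation was tested.

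Counts of the ribosomal RNA locus on chromosome 17, per protein-coding count, were 3.21 log2 units higher in replicate 2 than in replicate 1 and 2.48 higher in replicate 3 than in replicate 1. If more cytoplasm had been carried into those fractions, mitochondrial RNA should have moved with it; it differed by 0.28 and -0.23 by counts and by 0.77 and 0.30 with the other quantifier, at most 0.201 of the difference of the locus. After the GC correction the locus differed by 1.70 and 1.17 and mitochondrial RNA by 1.16 and 0.50, which is 0.684 and 0.427 of the locus, so these values disagree and carry-over of cytoplasm stays open, although ribosomal protein mRNAs differed by between -0.07 and 0.41 over all settings, the GC correction included. The starting amount of RNA cannot be told apart from the replicate, with 1.0 library per amount, and may be the source. No biological explanation was tested, nor was the efficiency of ribosomal RNA depletion.

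Among mitochondrial mRNAs, mt-Atp6 was at 0 and mt-Co3 at 0.07 TPM in the alignment-based values, against 34.0 and 35.5 in the alignment-free ones. A candidate explanation is that reads were given to nuclear copies: a median of 99.7% of the 31-base words of these 2 mRNAs occur in annotated nuclear genes, against 16.8% for the other 11. The copies are Gm10925 (chromosome 1, 24613974 to 24614651), at 44.4 TPM alignment-based and 0.03 alignment-free, and Gm28437 (24613189 to 24613971), at 87.7 and 27.3. The medians rest on 2 mRNAs, but other values went in the same direction. With 100.0%, 98.1% and 98.9% of their words in nuclear genes, mt-Co2, mt-Nd3 and mt-Nd4l were at 0.37, 0.201 and 0.698 of the alignment-free TPM. The remaining mRNAs, with at most 63.9% of their words in nuclear genes, were at 1.346 to 2.526 of it. No biological explanation was tested.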
